A study of Mus musculus with 6 samples.

How the data were processed

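The 6 arrays measured total RNA from mouse embryos of embryonic day 8.5 (median somite number 6) that carried a GFP reporter at the Noto locus, a homeobox gene of the node and the cells that form the notochord. Per the labels' protocols, tissue behind the first somites was dissected, pooled from 23, 39 or 52 embryos, dissociated in 1% trypsin and sorted into GFP-positive and GFP-negative cells. About 2600, 4300 and 6600 GFP-positive cells were collected from the 3 pools. RNA was extracted with a carrier, amplified through both rounds of an Affymetrix labeling kit and hybridized with a biotin label. Each pool gave 1 GFP-positive and 1 GFP-negative array, so each group holds 3 arrays of separate embryo pools.

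The deposited values are 1-colour array intensities on a linear scale, processed with GCOS 1.4, per the submitters' processing notes. Their values show that each array was scaled to 1 common level: the mean intensity, with 2% of probe sets trimmed at each end, was 150 on all 6 arrays. Medians of the deposited intensities lay between 19.8 and 28.0. Detection calls were not used here, so a low value may be background, and the number of arrays limits the precision. The table held 45101 probe sets, of which 64 were controls. The platform annotation gave 1 gene symbol for 34945 probe sets and several for 932, and 9160 were unnamed here; genes were named only from probe sets with 1 symbol. Of these, 34754 were found by gene identifier in the RefSeq table (assembly GRCm38.p6), and no symbol needed an update. No coordinates were used, since no build is named for the values. No per-sample column was left unused (0 columns). The reporter gene Noto had no probe set named here and was not analysed here.

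Intensities were taken to log2(value + 32), so fold changes understate the change of dim genes. A probe set was kept if at least 3 of the 6 arrays had it at or above that array's 40th percentile. The 27821 kept probe sets were fitted with limma 3.58.1 (lmFit, eBayes with a variance trend) with group as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Each of 12628 genes was represented by its kept probe set with the highest mean, and p-values were adjusted again over genes. Of the 588 genes that passed, 266 had other kept probe sets; for 44 of these, at least 1 other probe set had the opposite sign, and in 0 cases did that probe set pass the test. Errors of log2 fold changes are standard errors from limma, and errors of intensities are SDs over 3 arrays.

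Gene lists were fixed before the data were examined: 20 lists of pathways, structures and cell type markers. Each was tested with limma's camera at a preset correlation of 0.01 and adjusted over the 20 lists, with an estimated correlation and fry beside it. Camera compares a list with the other genes, whereas fry tests a list against no change, so their p-values answer different questions. For each list the members that passed are counted over all genes and adjusted over the list alone. Named genes followed a rule of the same date: all measured genes of the node and notochord list, the 12 largest increases and 8 largest decreases among genes that passed with 1 sign in all 3 pools, and for each other list the 3 members with the smallest adjusted p, or the 2 with the largest change where none passed, and any gene that a count of 5 or fewer consists of. Genes outside the rule are said to be so.

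Same-numbered arrays came from the same pool of embryos, per the labels, so the numbers pair the samples. Their deviations from the group means correlated at 0.542, 0.286 and 0.436 over kept probe sets. Between GFP-positive and GFP-negative arrays of different pools these correlations lay between -0.523 and 0.38. The fit without the pool as a block was the one planned to be reported. The blocked value is printed where it changes a list's call or moves a count by more than 1.5 times. It is printed for some, not all, of the named genes whose call it changes.

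RNA quality was read from the Gapdh and beta-actin control probe sets as 3′ over 5′ signal ratios, with an exact permutation test (two-sided; 3 against 3 arrays cannot give a p under 0.1) and, added after seeing the data, an exact sign-flip test within pools, which cannot give a p under 0.25. Alternatives were the offset, the normalization between arrays, the filter, the variance model, the pool as a replicate block, other thresholds, the mean over a gene's probe sets, each array left out, and each pool left out. Software was R 4.3.3 and Python 3.11.15.

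The fit was tested on simulated data with the real pool effects and no group effect, in which 200 probe sets changed by 2-fold or 4-fold in each of 10 draws. With variances drawn from the fitted prior, the fit without the block found 52.7% of the 4-fold and 0.5% of the 2-fold changes over 28082 probe sets, and 0.561% of its calls were false. The blocked fit found 77.6% and 12.9%, with 3.62% of calls false. With each probe set's own posterior variance in place of the prior, 13.6% of the blocked fit's calls were false over 27972 probe sets, and 0% without the block. In 400 list tests on data simulated without a group effect, camera gave an unadjusted p under 0.05 in 4.25%. The simulated noise was independent between probe sets, so this rate does not cover lists of correlated genes. In the real data the estimated correlation was 0.125 for the node list and 0.585 for endothelium and blood.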

Results

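Sorted cells from the posterior of embryonic day 8.5 mouse embryos were compared. The question was which genes distinguish GFP-positive cells, sorted by the Noto-GFP reporter, from the GFP-negative cells of the same tissue. The data are 3 arrays of GFP-positive and 3 arrays of GFP-negative cells, 1 of each from every pool of 23, 39 and 52 embryos. Over the kept probe sets, array values correlated between 0.889 (GFP-positive pool 1 with GFP-negative pool 3) and 0.991 (GFP-positive pools 2 and 3). The first principal component held 53.0% of the variance and the second 29.8%. The first did not separate the sorted groups. GFP-negative array 1 lay at -24.2, among the GFP-positive arrays (-56.2, -25.7 and -22.2), and GFP-negative arrays 2 and 3 lay at 54.6 and 73.8. GFP-negative array 1 correlated at 0.964 with GFP-positive array 1, and at 0.938 and 0.914 with GFP-negative arrays 2 and 3.

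Both arrays of pool 1 differed from the other 4 in RNA quality. The Gapdh 3′ over 5′ ratio was 14 and 15.4 on the GFP-positive and GFP-negative arrays of pool 1, and between 1.60 and 2.22 on the other arrays. The beta-actin ratio was 14.9 and 22.7 in pool 1, and between 1.90 and 2.75 elsewhere. Between the groups, the mean log2 ratio was 1.84 ± 1.74 (SD, n = 3) in GFP-positive and 2.15 ± 1.80 (SD, n = 3) in GFP-negative arrays. The exact permutation test between all arrays gave p = 0.5, and the smallest p it allows is 0.1. Within pools the GFP-positive array had the lower mean ratio in 3 of 3, by log2 differences of -0.37, -0.12 and -0.46; an exact sign-flip test, added after seeing the data, gave p = 0.25, the smallest it allows.

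**Figure D1:**
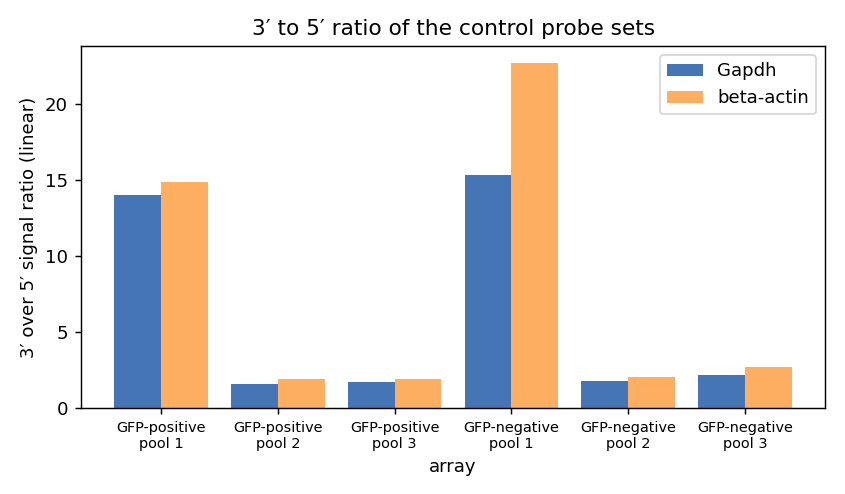
Bars give the 3′ over 5′ signal ratio (linear) of the Gapdh and beta-actin control probe sets on each of the 6 arrays. Both pool 1 arrays lie at 14 or above, and the other 4 at 2.75 or below.

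Node and notochord genes were higher as a list in GFP-positive cells, and the lists of lateral mesoderm and of endothelium and blood were lower. All 3 passed camera at its preset correlation and none at an estimated one (adjusted p = 0.0789, 0.0789 and 0.229). Shh, the secreted signal of the notochord, had a mean intensity of 5177 ± 562 (SD, n = 3) in GFP-positive and 271 ± 197 in GFP-negative arrays. Tbx20, a T-box factor of heart and lateral mesoderm, had 67.9 ± 26.8 against 1822 ± 1031. Of 12628 genes, 372 were higher and 216 lower in GFP-positive cells at an adjusted p under 0.05, and 275 and 156 of them by at least 2-fold. Of 27821 probe sets, 350 were higher and 153 lower. With the pool as a block, 980 genes were higher and 757 lower, which include all 372 and 216, and 1372 and 1371 probe sets passed.

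These counts depended on single arrays and pools. Without pool 1, whose control ratios stood apart, 2369 genes were higher and 2137 lower; without pool 2 the counts were 4 (Defa31, Cthrc1, Foxa1 and Bicc1) and 0, and without pool 3 they were 38 and 7. Leaving out 1 array gave 67 and 16 genes without GFP-positive array 3, 72 and 20 without GFP-positive array 2, 73 and 17 without GFP-negative array 2, 133 and 39 without GFP-negative array 3, and 1389 and 1342 without GFP-negative array 1. The 2369 and 2137 genes found without pool 1 held 299 of the 372 higher and 188 of the 216 lower genes. The filter asked for 3 arrays also when arrays were left out, so some genes were no longer tested. All 588 genes that passed had the same sign in all 3 pools, which selection by a test on these same arrays favours.

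Genes of the node and notochord rose as a group. Of 26 genes listed, 22 had a named probe set and 21 were measured. Over all genes 13 were higher, 0 lower and 8 did not pass; adjusted over the list alone, 17 were higher and 1 lower. Beside Shh, with a log2 fold change of 4.45 ± 0.58 (SE, adjusted p = 0.00694), the forkhead factors Foxa1 and Foxa2 rose by 4.13 ± 0.27 and 3.64 ± 0.23 (adjusted p = 0.000317 for each). Shh differed within pools by 6.20, 3.62 and 3.51, and its value was 3.65 without GFP-negative array 1 and 3.57 without pool 1. Nodal, the signal that surrounds the node, rose by 3.18 ± 0.21. Bicc1, an RNA-binding protein of the node, rose by 3.58 ± 0.23, and Slit2, a secreted guidance cue, by 3.15 ± 0.33. Krt19 rose by 2.88 ± 0.37, Krt8 by 1.25 ± 0.18, the Nodal antagonist Dand5 by 1.89 ± 0.28 and the BMP antagonist Chrd by 1.64 ± 0.28. The cartilage and notochord genes Sox9, Col2a1 and Sox6 rose by 1.79 ± 0.25, 1.4 ± 0.20 and 1.00 ± 0.20. Camera gave an adjusted p of 3.11e-15 for the list, and adjusted p = 0.0789 with an estimated correlation.

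The remaining members of this list did not pass over all genes. Log2 fold changes were 0.98 ± 0.25 for Krt18, 0.74 ± 0.20 for Cfc1, 0.78 ± 0.25 for Foxd4, 0.46 ± 0.19 for Foxj1, 0.25 ± 0.17 for Lhx1, 0.19 ± 0.15 for Nog, 0.03 ± 0.14 for Sox5 and -0.43 ± 0.17 for Cd24a, the 1 gene lower when adjusted over the list alone. With the pool as a block, Krt18 (adjusted p = 0.0214) and Cfc1 (adjusted p = 0.0361) passed. The probe set of Sox5 disagreed in sign with 3 of its 4 other kept probe sets, that of Cd24a with 1 of 2 (at 0.73) and that of Lhx1 with its 1 other (at -0.16).

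**Figure D2:**
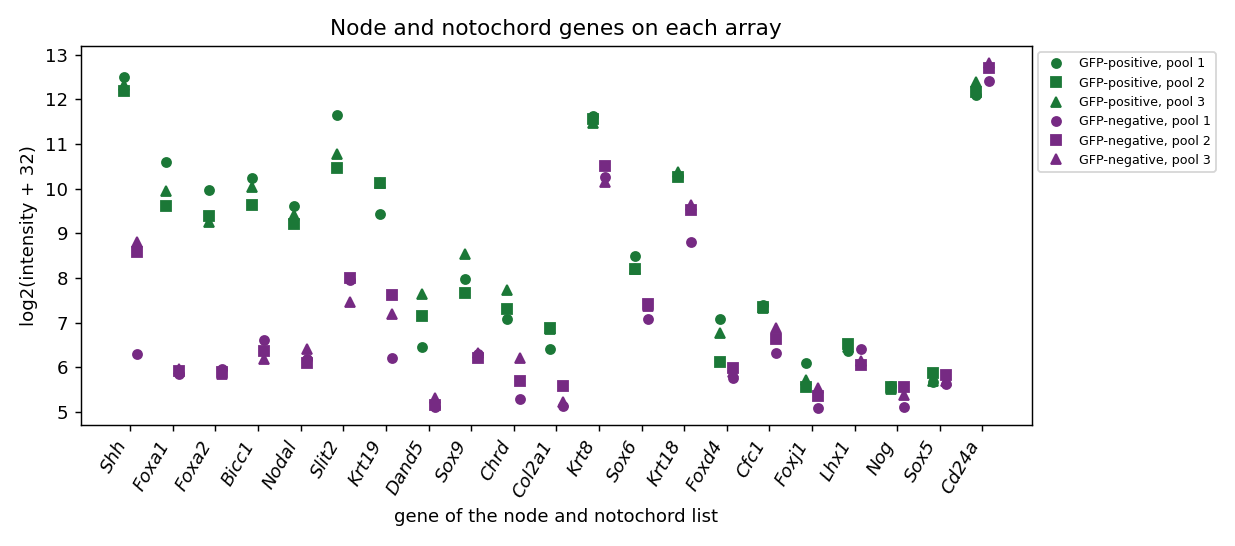
Points give log2(intensity + 32) on each array for the 21 measured node and notochord genes, with colour for the sorted group and shape for the pool. For Shh, Foxa1, Foxa2 and Nodal every GFP-positive array lies above every GFP-negative array, while Sox5 and Nog overlap.

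The largest increase outside this list was Defa31, an alpha-defensin, at 6.05 ± 0.25 (adjusted p = 2.91e-05); its probe set is of a type that can bind several related sequences, so the family member is uncertain. Cthrc1, a secreted collagen triple helix repeat protein, rose by 5.03 ± 0.27, from 71.9 ± 11 to 3487 ± 1261 in mean intensity. Vtn, the matrix and plasma protein vitronectin, rose by 4.24 ± 0.17; its other kept probe set rose by 2.11, and stood for the gene, at 2.03 to 2.17, without any 1 GFP-positive array and without pool 2 or 3. The membrane serine protease Tmprss2 rose by 3.59 ± 0.24, the transglutaminase Tgm2 by 3.09 ± 0.24 and the monooxygenase Moxd1 by 3.07 ± 0.23. Among the largest decreases, log2 fold changes were -4.04 ± 0.47 for Tbx20, -3.87 ± 0.74 for Hemgn, a nuclear protein of blood cells, and -3.15 ± 0.48 for Tbx4, a T-box factor of hindlimb and allantois. Kdr, the VEGF receptor of endothelium, changed by -2.94 ± 0.33, and Snai2, a factor of migrating mesenchyme, by -2.83 ± 0.30. Values were -2.44 ± 0.43 for Col3a1, -2.39 ± 0.42 for Pmp22 and -2.36 ± 0.31 for Hapln1. Without GFP-negative array 1 the values were -4.83 for Hemgn, -4.62 for Tbx20 and -3.75 for Tbx4; without pool 1 Hemgn had -4.56 and Tbx20 -4.83, and without GFP-negative array 3 Hemgn had -3.15 and did not pass (adjusted p = 0.0609).

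Genes of motile cilia, the structures that drive leftward flow at the node, were higher as a group. Of 41 measured, 11 were higher, 0 lower and 30 did not pass; adjusted over the list alone, 15 were higher. Cfap52 and Pifo rose by 1.80 ± 0.20 and 1.73 ± 0.22, and Tekt1, a protein of ciliary microtubules, by 1.03 ± 0.17. Camera gave an adjusted p of 3.50e-06, and adjusted p = 0.229 with an estimated correlation. Without pool 1 the adjusted p was 0.101.

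Among signalling lists, WNT genes passed the list test. Of 31 measured, 5 were higher and 0 lower, and adjusted over the list alone 9 were higher and 1, Sfrp2, lower. Prickle2, Sp5 and Nkd1 rose by 1.98 ± 0.23, 1.97 ± 0.22 and 1.57 ± 0.20, and Fzd7 and Prickle1 by 1.33 and 1.13; Sp5 and Nkd1 are known targets of the pathway. The other kept probe set of Fzd7 had the opposite sign, at -0.53, as did 1 of 3 others of Nkd1 and 1 of 2 of Prickle1. Camera gave an adjusted p of 0.00249, with adjusted p = 0.191 with an estimated correlation, 0.0521 without pool 1 and 0.0779 without GFP-negative array 1. Notch genes had an adjusted p of 0.0502, which passed with the pool as a block (adjusted p = 0.0327) and was 0.287 with an estimated correlation. Of 20 measured, 4 were higher and 0 lower, and adjusted over the list alone 8 and 2 (Dll4 and Dlk1). The probe set of Dlk1 is 1 of 23 that were bright only on GFP-negative arrays 2 and 3; without these, an alternative chosen after seeing the data, the Notch list had an adjusted p of 0.0201. The receptor Notch1 rose by 1.83 ± 0.21, its feedback inhibitor Nrarp by 1.36 ± 0.25 and the ligand Dll1 by 1.11 ± 0.21; the fourth was Hey1, at 0.91 and adjusted p = 0.0394.

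Hedgehog and TGF-beta, BMP and Nodal genes moved in both directions. Of 18 hedgehog genes, 2 were higher (Shh, and the transducer Smo at 1.01) and 2 lower, and adjusted over the list alone 4 (also Disp1 and Hhat) and 2. Foxf1, a target of the pathway in lateral mesoderm, fell by 2.11 ± 0.35, and Hhip, which binds the ligand, had -0.81 ± 0.17. As a list, hedgehog genes had an adjusted p of 0.159. Of 29 TGF-beta, BMP and Nodal genes, 6 were higher and 1, Msx1 at -1.16, was lower; adjusted over the list alone, 9 and 7. Nodal, Dand5 and the BMP and WNT antagonist Sostdc1 (1.39 ± 0.22) had the smallest adjusted p. The list's adjusted p was 0.52, and its median of -0.09 differed in sign from its mean of 0.22 and its test.

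Epithelial and junction genes were higher. Of 32 measured, 10 were higher and 0 lower, and adjusted over the list alone 17 and 1 (Crb3, whose other kept probe set had the opposite sign). Cdh1, the epithelial cadherin, rose by 1.98 ± 0.21 and the claudin Cldn9 by 1.61 ± 0.21, beside Krt19 above. Camera gave an adjusted p of 2.92e-07, and adjusted p = 0.191 with an estimated correlation. Of 35 basement membrane and matrix genes, 7 were higher and 3 lower, and adjusted over the list alone 13 and 3. Comp, a cartilage matrix protein, rose by 1.76 ± 0.19 and Col2a1 as above, while Hapln1, a link protein of hyaluronan, fell; the other 2 that fell were Nid1 and Lama4, at -1.10 and -1.07. The adjusted p was 0.0137, and adjusted p = 0.277 with an estimated correlation; it was 0.283 without pool 1, 0.139 without GFP-negative array 1 and 0.0627 without GFP-positive array 1.

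Of the cell types that the tissue could hold, paraxial mesoderm, endoderm and streak lists were higher in GFP-positive cells. Of 26 presomitic and somite genes, 11 were higher, 1 lower and 14 did not pass, and adjusted over the list alone 17 and 1. Pcdh8, Ripply2 and Foxc1 rose by 1.89 ± 0.21, 1.5 ± 0.20 and 1.26 ± 0.21, while Tcf21 fell by 1.15 ± 0.20. Camera gave this list an adjusted p of 4.56e-08, and adjusted p = 0.0789 with an estimated correlation. Of 22 gut endoderm genes, 7 were higher and 1, Hhex at -1.47, was lower, and adjusted over the list alone 10 and 2 (Hhex and Hnf4a). Foxa1 and Krt19, which the node list also holds, and Apela, a secreted peptide, at 2.04 ± 0.27, led the list. For endoderm the adjusted p was 1.91e-05, and adjusted p = 0.277 with an estimated correlation. Of 22 streak and tail bud genes, 3 were higher and 1, Nkx1-2, lower, and adjusted over the list alone 9 and 2 (Nkx1-2 and Cdx4). Sp5, Mixl1 (1.68 ± 0.18) and Fgf8 (1.06 ± 0.20) were the 3. For the streak list the adjusted p was 0.00402, and adjusted p = 0.236 with an estimated correlation.

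Lists of lateral mesoderm and of endothelium and blood were lower. Of 21 lateral and intermediate mesoderm genes, 0 were higher and 12 lower, and adjusted over the list alone 16 were lower. Beside Tbx20, log2 fold changes were -1.72 ± 0.21 for Prrx1 and -1.54 ± 0.21 for Gata6. Camera gave 8.85e-14 as the adjusted p, and adjusted p = 0.0789 with an estimated correlation. Of 25 endothelial and blood genes, 0 were higher and 11 lower, and adjusted over the list alone 23 were lower. The endothelial factors Etv2 and Sox7 had -1.88 ± 0.25 and -1.45 ± 0.16, beside Kdr. The adjusted p was 3.11e-15, and adjusted p = 0.229 with an estimated correlation. The haemoglobin genes Hbb-y, Hbb-bh1 and Hba-x, chosen after their values were seen, did not pass over all genes (adjusted p = 0.0656, 0.0993 and 0.109) and did with the pool as a block (0.0106, 0.0173 and 0.00375), when 22 of the 25 were lower.

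Surface ectoderm genes were lower as a list, while neural plate and germ cell lists did not pass the list test. Of 22 neural plate genes, 0 were higher and 1, Nkx1-2 at -1.44 ± 0.31, lower, and adjusted over the list alone 1 (Hes5) and 4 (Nkx1-2, Pax6, Olig3 and Zic5). Pax6 and Olig3 had -0.61 ± 0.16 and -0.70 ± 0.19 and passed with the pool as a block (adjusted p = 0.0439 and 0.0308). The list's adjusted p was 0.74, and its median of 0.07 differed in sign from its mean of -0.01 and its test. Of 15 surface ectoderm genes, 1, Cdh1, was higher and 5 were lower. The 5 were Tfap2a (-1.39 ± 0.17), Dlx5 (-0.89 ± 0.15), Msx1, Gata3 (-0.73) and Trp63 (-1.01). Mean intensities of Dlx5 and Gata3 were only 32.4 and 32.2 on GFP-negative arrays, near the array medians, so both changes may lie within background. Adjusted over the list alone, 2 (Cdh1 and Perp) were higher and 8 lower. The adjusted p was 0.0214, and adjusted p = 0.236 with an estimated correlation, and it lay above 0.05 without pool 1, 2 or 3 (0.183, 0.254 and 0.191) and without GFP-negative array 1, 2 or 3 (0.147, 0.241 and 0.229). Of 16 germ cell genes, 0 were higher and 1, Prdm1 at -1.06 ± 0.23, lower, also when adjusted over the list alone. Kit and Tfap2c had -1.22 ± 0.39 and -1.11 ± 0.32 and passed with the block (adjusted p = 0.0129 and 0.00768). The list's adjusted p was 0.0699, with 0.0327 with the pool as a block and 0.277 with an estimated correlation.

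**Figure D3:**
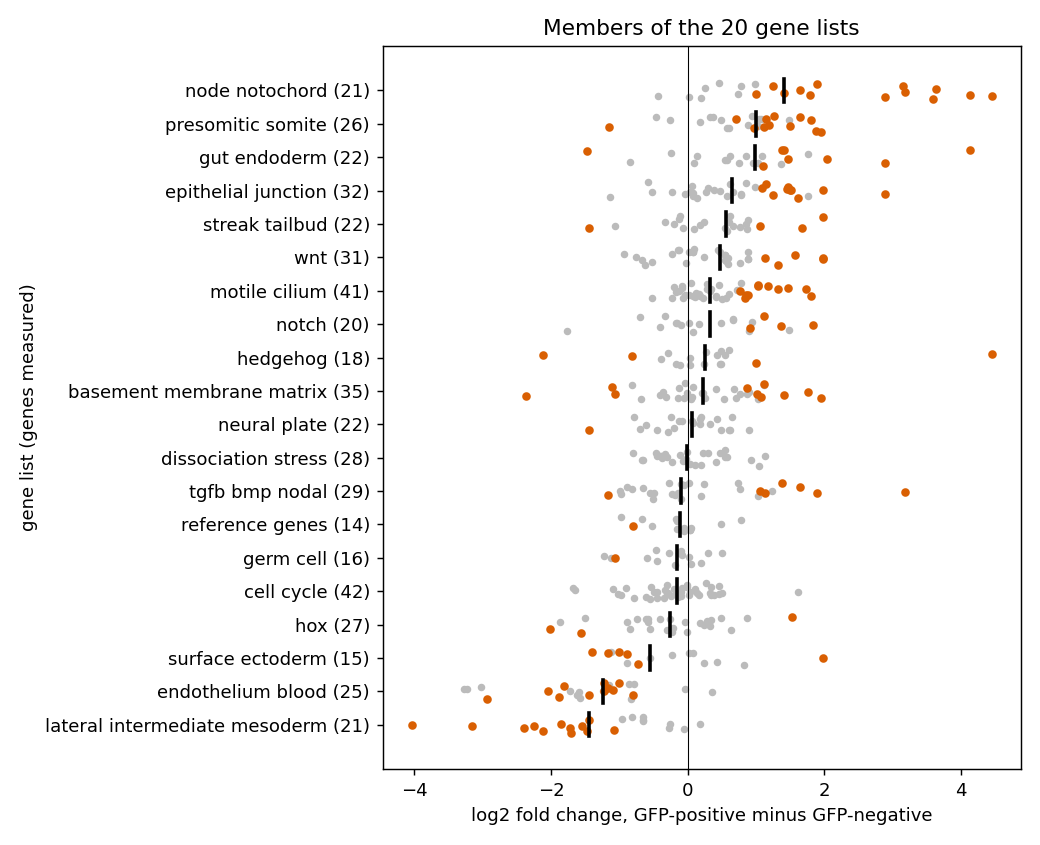
Points give each measured gene's log2 fold change, GFP-positive minus GFP-negative, for the 20 lists, with genes that passed over all genes in orange, others in grey and the list median as a black line. Medians run from -1.45 for lateral and intermediate mesoderm to 1.4 for node and notochord genes.

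Hox genes were lower as a list. Of 27 measured, 1 was higher and 2 lower, and adjusted over the list alone 2 (Hoxb1, and Hoxb4, whose other kept probe set had the opposite sign) and 5 (Hoxc9, Hoxc10, Hoxa10, Hoxa11 and Hoxd10). Hoxb1, an anterior member, rose by 1.53 ± 0.28, and the posterior members Hoxc9 and Hoxa10 fell, at -2.02 ± 0.30 and -1.56 ± 0.29. The adjusted p was 0.0374, and adjusted p = 0.277 with an estimated correlation; it was 0.636 without pool 1, 0.239 without GFP-positive array 1 and 0.215 without GFP-negative array 1. Of 42 cell cycle genes, 0 passed in limma over all genes, and 1 was higher and 7 lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 was higher (Ccnd1, 1.62) and 4 were lower (Mki67, Cenpf, Kif11 and Ccnd2). Mki67 and Cenpf had -1.68 ± 0.45 and -1.65 ± 0.39 and passed with the pool as a block (adjusted p = 0.0152 and 0.0232). For cell cycle genes as a list the adjusted p was 0.0457, and adjusted p = 0.277 with an estimated correlation; it was 0.26 without pool 1, 0.15 without GFP-positive array 1 and 0.245 without GFP-negative array 1.

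Of 28 genes that cell dissociation can induce, 0 passed in limma, over all genes or adjusted over the list alone, and 5 were higher and 4 lower at an unadjusted p under 0.05. The immediate early genes Ier2 and Egr1 had 1.12 ± 0.31 and 1.04 ± 0.35 and passed with the block (adjusted p = 0.00706 and 0.00789), when 3 genes were higher (also Fos) and 2 lower (Dnajb1, whose other kept probe set had the opposite sign, and Klf6). The list's adjusted p was 0.9, with a mean of 0.05 that differed in sign from its median of -0.02 and its test. Of 14 reference genes, 0 were higher and 1, Tfrc at -0.79 ± 0.18, lower, and adjusted over the list alone 1 (B2m) and 2 (Tfrc and Pgk1). B2m and Pgk1 had 0.77 ± 0.20 and -0.52 ± 0.15 and passed with the block (adjusted p = 0.0276 and 0.0462). As a list they had an adjusted p of 0.154.

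With the pool as a block, more members passed in most lists. Counts higher and lower were then 9 and 5 for TGF-beta, BMP and Nodal genes, 8 and 1 for WNT genes, 8 and 1 for Notch genes, 17 and 1 for epithelial genes, 13 and 4 for basement membrane genes and 11 and 1 for gut endoderm genes. They were 19 and 1 for presomitic and somite genes, 8 and 2 for streak and tail bud genes, 3 and 4 for neural plate genes, 2 and 7 for surface ectoderm genes, 0 and 4 for germ cell genes, 2 and 5 for Hox genes, 1 and 7 for cell cycle genes and 1 and 4 for reference genes. Members of these small counts not named above were Bmp4, Id2, Msx2 and Smad7 (TGF-beta, BMP and Nodal), Vcan (basement membrane), Sall4 (germ cell), Hoxc6 and Hoxd8 (Hox), and Hprt and Ywhaz (reference), all lower, and Cdh2 and Irx3 (neural plate), both higher. Of these, Sall4 had its 1 other kept probe set with the opposite sign and Ywhaz 3 of 6.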

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

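Most alternatives were planned; leaving out the probe sets bright on only 2 GFP-negative arrays, leaving out shared node genes and the test of RNA quality within pools were chosen after seeing the data. No cause of these changes was tested. Counts are given for genes higher and lower, then probe sets higher and lower. With the replicate block they were 980, 757, 1372 and 1371; without a filter 233, 101, 185 and 67; and at an adjusted p under 0.01 they were 92, 22, 83 and 10. Leaving out an array or a pool gave 4 to 2369, 0 to 2137, 2 to 3563 and 0 to 4080, highest without pool 1 and lowest without pool 2. Other settings stayed within 1.5 times, and without the probe sets bright on 2 arrays 375 and 221 genes passed. With an estimated correlation no list passed: adjusted p was 0.0789 for node, presomitic and lateral mesoderm lists, 0.191 for WNT and epithelial genes, 0.229 for cilium and endothelium and blood, 0.236 for streak and surface ectoderm, and 0.277 for basement membrane, endoderm, Hox and cell cycle genes. Notch passed with offset 1 (0.0365), the larger offset (0.0474), no filter (0.00975), the 60th percentile (0.0146), no variance trend (0.0412), the replicate block (0.0327), fry (0.0261) and without the bright probe sets (0.0201), and ranged from 0.0238 to 0.195 over arrays and pools left out. Germ cell genes passed at the 60th percentile (0.0219) and with the block (0.0327), with 0.0266 to 0.239 over arrays and pools left out. Surface ectoderm was lost at the 60th percentile (0.278), range 0.0256 to 0.254. Cell cycle genes were lost without a filter (0.161), with the mean over probe sets (0.0873) and with fry (0.0878), range 0.00788 to 0.26. Hox was lost with fry (0.117), range 0.002 to 0.636. Ranges for the other lists whose call or direction moved were 4.58e-08 to 0.101 for cilium, 0.000525 to 0.0779 for WNT, 0.00203 to 0.283 for basement membrane, 0.33 to 0.997 for TGF-beta, 0.191 to 0.929 for neural plate and 0.526 to 0.954 for dissociation genes. TGF-beta genes passed with fry (0.0275) and turned direction without shared node genes (0.343). The dissociation list turned, never passing, without a filter (0.757), with the block (0.945), with the mean over probe sets (0.864) and with fry (0.914). Node, epithelial, endoderm, presomitic, streak, lateral mesoderm, and endothelium and blood lists kept direction and call in every setting but the estimated correlation. Of 138 named genes, which include those named because they passed with the block, the block added 42 calls and lost 0, and changed no other named call. Calls of named genes were lost for 69 of 125 without pool 2, 52 of 127 without pool 3, 43 and 27 of 136 without GFP-negative array 2 or 3, and 41, 38 and 16 of 131 without GFP-positive array 3, 2 or 1, where 4 were gained. None was lost without pool 1 (48 gained) or GFP-negative array 1 (40 gained of 136). Among 138, calls lost were 14 without a filter, 9 with the mean over probe sets (3 gained), 5 with the larger offset, 3 with offset 1, 3 without a variance trend (2 gained), 2 with median centring (1 gained), 1 with quantile normalization (2 gained) and 1 with robust variances; the 60th percentile lost 0 and gained 2 among those it kept, and leaving out the bright probe sets changed 0 of 137. Sox5 turned sign with the larger offset (-0.000989), with the mean over probe sets (-0.221) and over arrays left out (-0.105 to 0.148); Cd24a did with the mean over probe sets (0.0619), and Lhx1 ranged from -0.0779 to 0.395. The group difference in the 3′ over 5′ ratio kept its sign with each control gene and with the middle probe set, and with the replicate block (-0.317) the within-pool p was 0.25.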

Other observations

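The genes in this paragraph were chosen after their values were seen. They are single genes, and no list of their kind was tested. Igfbp5, which binds insulin-like growth factors, rose by 2.85 ± 0.23 (log2, SE), while its 1 other kept probe set had the opposite sign. The selenium carrier Selenop rose by 2.71 ± 0.24, the neuropeptide Gal by 2.67 ± 0.20, the fibrinogen chain Fgg by 2.49 ± 0.20 and clusterin, Clu, by 2.46 ± 0.26. The transcription factors Foxd1 and Mnx1 rose by 2.45 ± 0.23 and 2.16 ± 0.21, and the guidance cue Ntn1 by 1.71 ± 0.24. Trp53inp1, a nuclear protein, and Cdkn1a, an inhibitor of the cell cycle, rose by 2.70 ± 0.37 and 1.53 ± 0.25. The fibrillar collagens Col1a1 and Col1a2 fell, at -1.70 ± 0.21 and -1.79 ± 0.41, and the log2 fold change of Plac1, a placental gene, was -2.25 ± 0.26. Each of these passed over all genes with the same sign in all 3 pools.

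All tests below except that on other probe sets of the same genes were chosen after the results were seen. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many genes (588), probe sets (503) or lists (13) as observed, and the highest of the other 9 gave 0 genes, 0 probe sets and 11 lists. The other splits that part all 3 pools gave 0 genes with the pool as a block, against 1737. Each of the other 9 keeps part of the sort contrast, with 2 arrays of 1 sorted group and 1 of the other on each side.

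The presomitic and somite list was higher in GFP-positive cells at camera's preset correlation but not at an estimated one (adjusted p = 0.0789), with 11 of 26 members higher, 1 (Tcf21) lower and 14 not passing. Random carry-over of GFP-negative cells can at most bring these transcripts to the GFP-negative level. The lowest of the pools' medians over the 26 was 0.766 above that level (SD over pools 0.232). This rise was known when the test was chosen, so the outcome was fixed and adds no separate evidence. The 3′ bias of pool 1 does not account for the rise either, since the lower median of pools 2 and 3 was 0.929. Selective entry of presomitic or somite cells into the gate stays open: the 11 bright members varied with an SD of 0.391 against a median standard error of 0.282, and other cells may express them too. Expression of these genes by the Noto-GFP cells themselves remains a hypothesis, which in situ hybridization for Pcdh8 and Ripply2 together with GFP would test.

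A group of 23 probe sets lay near background on 4 arrays and was bright on GFP-negative arrays 2 and 3, by a median of 3.24 log2 units. Without the block and adjusted over all probe sets, 0 of them were called lower. The median difference over all kept probe sets was 0.0218, so the rise was not shared by most probe sets. All arrays had been scaled to 1 common level, which largely set this value, so it cannot test an array-wide scaling difference. If cells present only in these libraries were the source, other probe sets of the same genes would rise. The 41 others rose by a median of 0.0693. The comparison was with other probe sets of lateral mesoderm, endothelial and blood genes that passed as lower in GFP-positive cells. Their difference was taken between all GFP-negative and all GFP-positive arrays, not between the same arrays as above. Its median was only 0.379, under the 0.5 set beforehand, so the test was not shown able to detect such cells and does not exclude them. A signal specific to these probe sets may be an alternative and was not tested.

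Haemoglobin signal on the GFP-positive arrays differed between pools. As shares of the GFP-negative intensity in pools 1, 2 and 3, Hbb-y stood at 2.30%, 28.2% and 14.1%, Hbb-bh1 at 2.67%, 45.3% and 12%, and Hba-x at 14.5% and 3.07% in pools 2 and 3; its GFP-positive value in pool 1 lay under that array's 40th percentile. The shares depend on the probe set: in pools 2 and 3 the dimmest of Hbb-y gave 9.00% and 2.65%, and that of Hbb-bh1 20.9% and 3.69%. The comparison used 10 bright lateral mesoderm and endothelial genes, taken only from those that passed as lower in GFP-positive cells. The haemoglobin genes had not passed, so these 10 were chosen for a low share. Of them, 1 (Tbx20, 1.80% and 2.71%) lay below the Hba-x share in both pools. Counts below the shares of other haemoglobin probe sets were 0 to 4, so random carry-over of GFP-negative cells stays open. Of 6 other erythroid genes, 1 (Hemgn, 2.69% and 1.41%) lay below the Hba-x share, and 1 to 6 below those of other probe sets. Klf1, Alas2 and Gata1 were dim, with 294, 310 and 317 on GFP-negative array 3. For each, 3.07% of that value would lie under 11.7, the 40th percentile of GFP-positive array 3. Background could thus hold them above the Hba-x share, so that count cannot decide. Whole erythroid cells in the sort stay possible as well.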
